A study of Mus musculus with 28 samples.

How the data were processed

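The samples were mouse peritoneal mast cells (PMC) that carried an HA tag on the ribosomal protein Rpl22 in mast cells (RiboTag), so that an anti-HA antibody pulls down their ribosomes with the mRNA on them. Per the labels, the mast cells were grown for 5 to 6 weeks, loaded with IgE at 0.5 µg per ml, and degranulated with 100 ng of DNP-HSA. PMC samples were kept without neutrophils, and MIT samples were mast cells from co-cultures with neutrophils; the labels do not spell out MIT. Sorting took place 2 h after degranulation, 60000 sorted cells went into each sample, 4 µg of antibody was used, and RNA was taken at 12 or 24 h. Each cell group and time had 3 kinds of pulldown, which were anti-HA from RiboTag cells, an isotype antibody from RiboTag cells, and anti-HA from cells without the tag. Titles and tag fields of all PMC RiboTag samples name the tag, but their source name reads PMC WT, and groups followed the titles. This made 12 groups and 28 libraries, of which 10 were RiboTag anti-HA, 10 isotype and 8 no-tag. Per cell group, the RiboTag anti-HA and isotype pulldowns had 2 libraries at 12 h and 3 at 24 h, and the no-tag pulldowns had 2 at each time. Input RNA, 10% of each lysate per the labels, was not analysed here.

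The deposited values are raw counts per gene, as whole numbers, with 1 column per library and no normalization. The submitters' processing notes name the genome build mm10 and DESeq2 without a version. The aligner, the counting tool, the annotation and the strandedness are not given in the sources used here. Levels of genes with related copies or pseudogenes, such as the tryptases, ribosomal protein genes, Ftl1, Hspa8 and Ybx1, and of overlapping or antisense genes such as Kcnq1ot1, are therefore uncertain. The table holds 47937 gene identifiers, of which 47224 were matched without their version number to GENCODE M21 (GRCm38) for symbols, positions and lengths, and the 713 unmatched ones held 0.0993% of the counts. All columns were assigned to a sample.

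RiboTag anti-HA libraries held 26737195 to 57884270 counts over 17858 to 22206 genes. The 18 control libraries held 90745 to 3652350 counts over 10259 to 29297 genes, and the ratio of the median totals was 77.6. A count of 3, taken as the floor of detection, came to 0.0518 to 0.112 CPM in the RiboTag anti-HA libraries and 0.821 to 33.1 CPM in the controls. Levels are given as CPM computed from the library totals, as mean ± SD over libraries. Intervals and floors cover counting error only, since no molecular identifiers are given.

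Fits used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3, with TMM factors, the expression filter by group, robust quasi-likelihood F-tests and Benjamini-Hochberg adjustment over all genes tested, and a threshold of 0.05. The 10 RiboTag anti-HA libraries were fitted alone for the comparison of MIT with PMC (both times averaged, 12 h, 24 h, and the difference between these effects) and of 24 h with 12 h in each cell group, over 14173 genes. All 28 libraries were fitted together for anti-HA against each control in each cell group, for MIT against PMC within each control, and for the difference between the effect in anti-HA and in each control, over 12023 genes. Standard errors of log2 folds are the size of the fold divided by the square root of F. Pooled count ratios have exact 95% intervals, and a fold against a group at 0 is taken against 3 counts over the pooled libraries.

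The labels carry a code, E1 or E2, that was read as a possible batch: 4 of the RiboTag anti-HA libraries, 1 per group, have E1 and 6 have E2. Whether replicates came from separate mice or cultures is not stated, so p-values measure only the spread between these samples, which may be technical. In MIT at 24 h, anti-HA replicates 2 and 3 differed least, with a chi-squared per degree of freedom of 2.60 against 13.7 to 53.0 in the other anti-HA replicate pairs; both were kept as separate libraries.

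Of 33 gene lists with 646 members, 644 members were found. The lists were mast cell identity and granules; neutrophil, monocyte and macrophage, lymphocyte, basophil and eosinophil, erythroid, and fibroblast and mesothelial markers; mitochondrially encoded mRNAs and nuclear noncoding RNAs; glycolysis, TCA cycle, nuclear encoded OXPHOS, fatty acid oxidation, cholesterol biosynthesis, LXR targets and lipid handling, and nucleotide synthesis and salvage. Further lists were lysosome, autophagy, phagocytosis and efferocytosis, amino acid stress and ATF4 targets, cytosolic ribosomal proteins, mast cell cytokines and mediators, immediate early genes, NF-kB targets, interferon response and IgE receptor signalling. The last were NRF2 targets and pentose phosphate, iron and haem handling, unfolded protein response, heat shock, hypoxia, apoptosis regulators and cell cycle. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone.

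Genes were named by a rule: per comparison the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 10 CPM, up to 4 members per list with the smallest p, and always Rpl22, Kit, Cpa3, Fcer1a, Mcpt4, S100a8, S100a9, Lcn2, Retnlg, Malat1 and mt-Co1. The text gives those whose counts allow a fold, and for some of them the level against the controls. Some of the genes this rule picked are not reported here. The comparisons, lists, naming rule and alternatives, except those named as added, were chosen before the data were examined.

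Alternatives were the E code as an additive term, DESeq2 1.42.0, RLE factors, no filter on low counts, a filter of at least 5 CPM, voom with sample quality weights, leaving out each library, all 28 libraries in the fit, and only genes enriched over both controls. DESeq2 was run on all genes with any count, so its counts, shares and medians cover more genes than the main fits. Added after the data were seen were only genes enriched over isotype, summing MIT 24 h replicates 2 and 3, thinning the anti-HA libraries to the median control total, and removing the transcript length trend per library. The fits were tested on simulated data with 200 changed genes. Apart from these genes, the simulated libraries shared 1 mean profile and had no effect of the E code. The rates below may therefore not hold for the real data. In simulated MIT against PMC over both times, 65.3% of 98 genes changed by 1.5-fold and 84.0% of 100 changed by 2-fold were found, with 6.33% false calls. For 24 h against 12 h in PMC, 30.0% and 68.0% were found, with 2.04% false. For anti-HA over isotype in MIT, 16.7% of 2-fold and 93.8% of 16-fold changes were found, with 3.70% false. For the difference between the effects in anti-HA and isotype, 3.45% of 2-fold and 90.4% of 16-fold changes were found, with 4.35% false.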

Results

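RiboTag anti-HA libraries, which hold RNA bound to mast cell ribosomes, had 26737195 to 35431865 counts in MIT and 30973273 to 57884270 in PMC (n = 5 each). Isotype pulldowns had 173008 to 449178 counts in MIT and 233882 to 1523966 in PMC (n = 5 each), and no-tag pulldowns 390382 to 654750 and 90745 to 3652350 (n = 4 each). The 22 mast cell genes took 16.5% ± 0.234 (SD) of the counts in MIT anti-HA and 17.8% ± 0.490 in PMC anti-HA, against 8.51% and 11.03% in the isotype pulldowns. In the no-tag pulldowns they took 13.17% in MIT and 14.67% in PMC. On log2 CPM, the first principal component of the 10 anti-HA libraries held 41.3% of the variance and the second 21.7%.

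**Figure D1:**
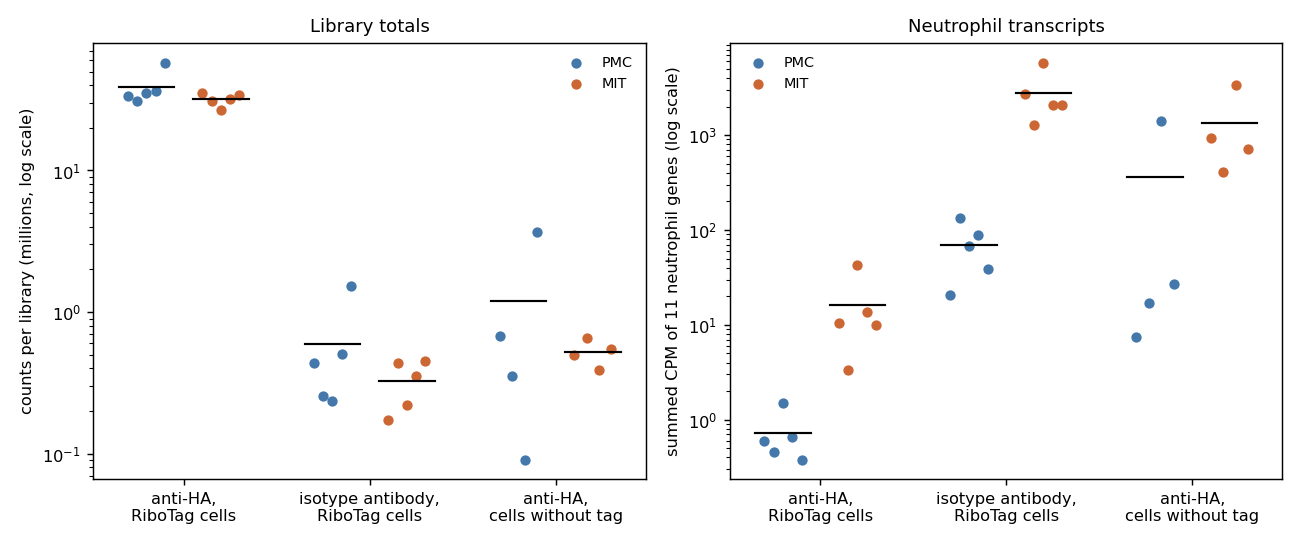
Counts per library (left) and summed CPM of the 11 neutrophil genes called higher in MIT anti-HA (right), for each library by pulldown and cell group. Both axes are log, and bars are means. The choice of genes fixes the direction of the gap between MIT and PMC in anti-HA. All 10 anti-HA libraries of RiboTag cells lie above all 18 controls in total counts, and neutrophil transcripts are highest in the MIT isotype pulldowns (mean 2804 CPM).

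Between MIT and PMC anti-HA libraries, transcripts of the mast cell's growth factor receptor and of granule contents differed in both directions. Kit, which encodes the receptor for stem cell factor, was 1.81-fold lower in MIT (3515 ± 226 against 6204 ± 342 CPM, SD, n = 5 each, log2 -0.86 ± 0.0602 SE; adjusted p = 0.000217 by edgeR's quasi-likelihood test with Benjamini-Hochberg, chromosome 5, 75574916 to 75656722, GRCm38). Cpa3, the granule carboxypeptidase, was 1.61-fold lower (32610 ± 8270 against 50170 ± 7110 CPM, log2 -0.68 ± 0.145, edgeR adjusted p = 0.00493 with Benjamini-Hochberg, chromosome 3, 20215620 to 20242181). Slc18a2, the transporter that loads amines into granules, was at 608 ± 110 against 865 ± 82.2 CPM (log2 -0.58 ± 0.0554). The receptor gene Mrgprb1 was at 2290 ± 156 against 3144 ± 72.8 (log2 -0.49 ± 0.0583), and the mast cell transcription factor gene Mitf at 186 ± 18.9 against 251 ± 15.8 (log2 -0.48 ± 0.0651). Mcpt4, the chymase gene, was instead higher in MIT, at 8025 ± 873 against 6351 ± 420 CPM (log2 0.30 ± 0.0722, edgeR adjusted p = 0.00921 with Benjamini-Hochberg). At each time the MIT libraries lay on 1 side of the PMC libraries for these 6 genes. Within E1 and E2, the log2 differences were -0.71 and -0.96 for Kit, -0.55 and -0.81 for Cpa3, -0.47 and -0.66 for Slc18a2, and 0.18 and 0.38 for Mcpt4. Within the isotype and no-tag pulldowns, MIT differed from PMC by log2 -1.03 and -0.80 for Kit and -0.86 and -0.55 for Cpa3. For Mcpt4 these were -0.06 and 0.26, and of all these values only that of Kit in isotype passed the threshold. A difference particular to ribosome-bound RNA was therefore not shown for Kit and Cpa3. Cpa3, Mrgprb1, Mitf and Mcpt4 were enriched over isotype in MIT. Kit (log2 0.44, edgeR adjusted p = 0.0944 with Benjamini-Hochberg) and Slc18a2 (log2 0.02) were not. Among the 6 only Mcpt4 was also enriched over no-tag in MIT. Kit passed the threshold over isotype without MIT isotype 12 h replicate 1 (log2 1.26) or 24 h replicate 1 (0.73) or 3 (0.77).

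Fcer1a, the IgE-binding chain of the high affinity receptor, was at 4448 ± 1230 CPM in MIT and 3637 ± 756 in PMC (n = 5 each, log2 0.21 ± 0.0731, 0.14 in E1 and 0.26 in E2, edgeR adjusted p = 0.0444 with Benjamini-Hochberg). That call was lost without MIT 12 h replicate 1 (log2 0.13), MIT 24 h replicate 2 (0.20) or 3 (0.19), PMC 12 h replicate 2 (0.12), or PMC 24 h replicate 1 (0.20), 2 (0.20) or 3 (0.21). Of 22 genes of mast cell identity and granules, 3 were higher and 13 lower in MIT (4 and 14 adjusted over the list alone, median log2 -0.28, -0.20 in E1 and -0.32 in E2). The list passed edgeR's camera test with Benjamini-Hochberg at adjusted p = 0.0057, but not with its members' own correlation, at adjusted p = 0.638 with an estimated correlation.

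**Figure D2:**
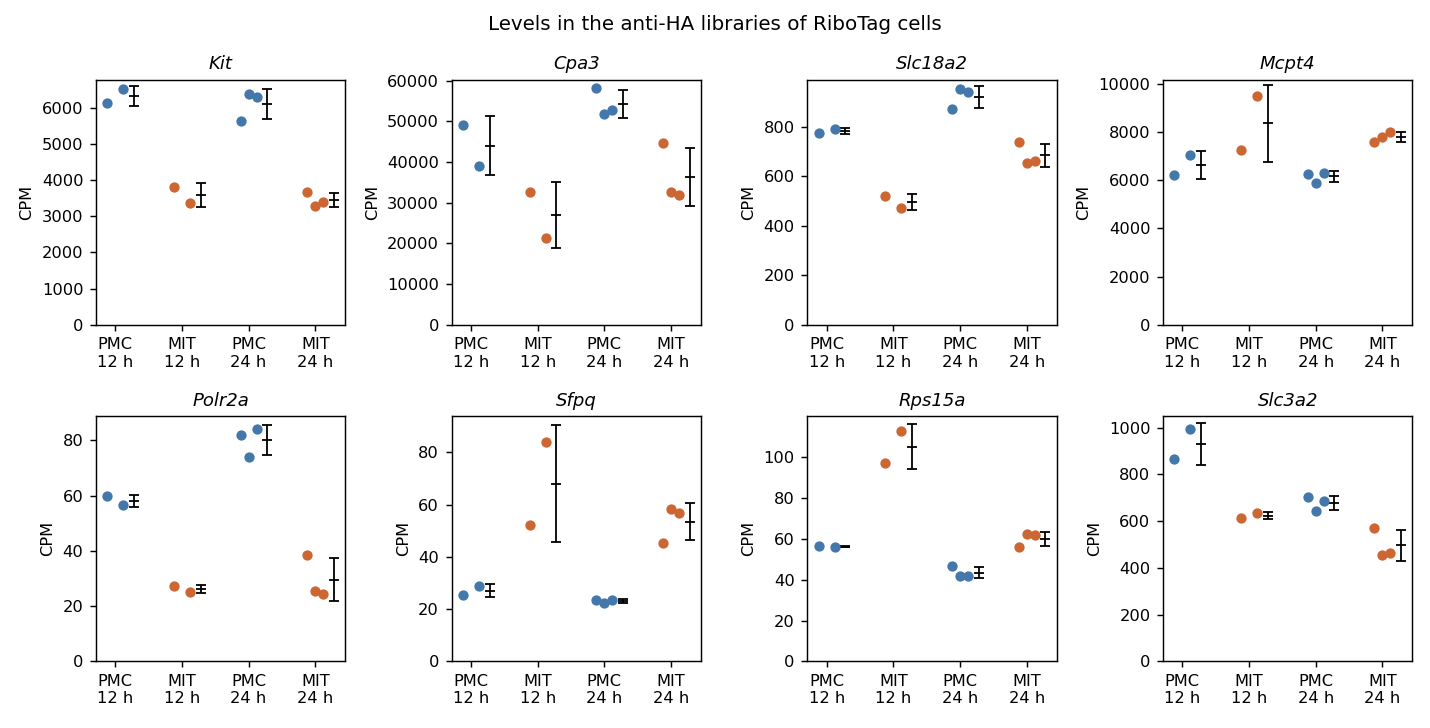
CPM of 8 genes in each RiboTag anti-HA library, by cell group and time, with mean and SD beside the points (n = 2 at 12 h, n = 3 at 24 h). Kit, Cpa3, Slc18a2, Polr2a and Slc3a2 lie lower in MIT and Mcpt4, Sfpq and Rps15a higher at both times.

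Transcripts for cytosolic ribosomal proteins and elongation factors were higher in MIT. Rps15a, of the small ribosomal subunit, was at 78.0 ± 25.4 CPM in MIT and 48.5 ± 7.28 in PMC (n = 5 each, log2 0.64 ± 0.0657, edgeR adjusted p = 0.00044 with Benjamini-Hochberg). Rps24 was at 111 ± 17.8 against 73.1 ± 3.74 (log2 0.59). Rpl22 itself, whose protein carries the tag, was at 37.0 ± 4.60 against 24.7 ± 2.12 CPM (log2 0.55 ± 0.0621, 0.61 in E1 and 0.51 in E2, edgeR adjusted p = 0.000519 with Benjamini-Hochberg, chromosome 4, 152325742 to 152334071). Of 54 genes for cytosolic ribosomal proteins and elongation factors, 51 were higher and 0 lower in MIT (51 and 0 adjusted over the list alone), with a median log2 difference of 0.40 (0.30 in E1 and 0.48 in E2). By camera the list reached adjusted p = 7.52e-18 with Benjamini-Hochberg on edgeR's log2 CPM, and adjusted p = 0.603 with an estimated correlation. With the transcript length trend removed per library, its median was 0.285. In MIT, Rpl22 was enriched over isotype, while Rps15a and Rps24 were not. None of these 3 was enriched over no-tag in the same cells. Reads of ribosomal protein genes may be shared with pseudogenes, which makes their levels uncertain.

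Nuclear genes for oxidative phosphorylation went the same way. Ndufa4, of the respiratory chain, was at 264 ± 17.2 CPM in MIT and 177 ± 14.8 in PMC (n = 5 each, log2 0.54 ± 0.059, edgeR adjusted p = 0.000489 with Benjamini-Hochberg). Ndufb9 of complex I was at 133 ± 10.7 against 97.6 ± 1.33 (log2 0.41), and Cox5a of complex IV at 254 ± 20.7 against 190 ± 5.20 (log2 0.39). Of 38 such genes, 30 were higher and 0 lower (30 and 0 adjusted over the list alone, median log2 0.33, 0.22 in E1 and 0.39 in E2). Camera gave adjusted p = 2.07e-08 with Benjamini-Hochberg, against adjusted p = 0.603 with an estimated correlation. With the transcript length trend removed per library, the median of the list was 0.181. All 3 named genes were enriched over isotype in MIT, and Ndufa4 also over no-tag. Mitochondrially encoded mRNAs, which cytosolic ribosomes do not translate, had 0 of 7 higher and 2 lower in MIT (0 and 2 adjusted over the list alone, median log2 -0.33; camera adjusted p = 0.295 with Benjamini-Hochberg). mt-Cytb was at 13.98 ± 3.13 against 27.2 ± 7.06 CPM (log2 -1.02 ± 0.203) and mt-Co1 at 10.7 ± 2.44 against 12.8 ± 2.65 (log2 -0.34 ± 0.185, edgeR adjusted p = 0.17 with Benjamini-Hochberg). Both were depleted against every control.

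Among lysosomal genes and targets of amino acid stress and ATF4, more were lower than higher in MIT. Lamp2, a protein of the lysosomal membrane, was at 467 ± 29.1 CPM in MIT and 681 ± 10.8 in PMC (n = 5 each, log2 -0.59 ± 0.0528, edgeR adjusted p = 0.000342 with Benjamini-Hochberg). The acid glucosidase gene Gaa was at 53.4 ± 7.65 against 87.5 ± 5.96 (log2 -0.74). The proton pump gene Atp6v0a1 was at 128 ± 15.7 against 202 ± 17.6 (log2 -0.70), and the protective protein gene Ctsa at 377 ± 65.6 against 511 ± 65.6 (log2 -0.50). Vacuolar ATPase subunits as a family, chosen after the results were seen, had 6 of 17 higher and 3 lower (median log2 0.04; camera adjusted p = 0.882 with Benjamini-Hochberg). The lysosome list had 2 of 35 genes higher and 19 lower (2 and 20 adjusted over the list alone, median log2 -0.24, -0.18 in E1 and -0.24 in E2; camera adjusted p = 0.000641 with Benjamini-Hochberg). By camera it did not hold at adjusted p = 0.603 with an estimated correlation. Slc3a2, the heavy chain of amino acid exchangers, was at 548 ± 83.9 against 779 ± 147 CPM (log2 -0.55 ± 0.0717, edgeR adjusted p = 0.000653 with Benjamini-Hochberg). The stress sensor gene Sesn2 was at 60.7 ± 11.5 against 98.4 ± 6.04 (log2 -0.75). The pseudokinase gene Trib3 was at 70.2 ± 22.3 against 102 ± 33.2 (log2 -0.58), and the cationic amino acid transporter gene Slc7a1 at 39.0 ± 3.23 against 52.3 ± 4.73 (log2 -0.46). Of 24 targets of amino acid stress and ATF4, 0 were higher and 15 lower (0 and 16 adjusted over the list alone, median log2 -0.40, -0.32 in E1 and -0.45 in E2; camera adjusted p = 0.000641 with Benjamini-Hochberg), against adjusted p = 0.644 with an estimated correlation. Lamp2 and Ctsa were enriched over isotype in MIT, and the other 6 genes here were not.

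**Figure D3:**
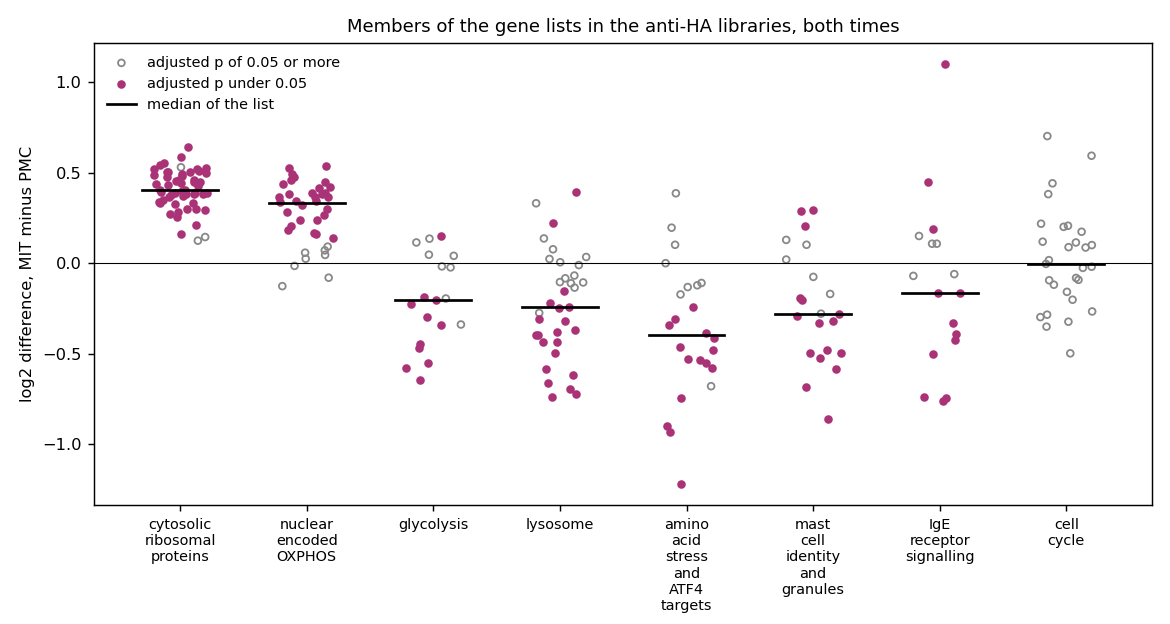
Log2 difference between MIT and PMC in the RiboTag anti-HA libraries for each tested member of 8 gene lists, with the list median as a bar; filled points have an adjusted p under 0.05. Medians range from -0.40 for ATF4 targets to 0.40 for ribosomal proteins.

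Single genes of other metabolic lists differed between MIT and PMC. Of all 14173 genes tested, 42.1% were called, and the counts per list below are to be read against that share. Slc2a1, a glucose transporter, was at 70.7 ± 1.19 CPM in MIT and 100 ± 11.2 in PMC (n = 5 each, log2 -0.55 ± 0.0719, edgeR adjusted p = 0.000675 with Benjamini-Hochberg). Pfkfb3, which makes an activator of glycolysis, was at 26.1 ± 4.78 against 35.5 ± 3.41 (log2 -0.47). Glycolysis had 1 of 19 genes higher and 10 lower (3 and 10 adjusted over the list alone, median log2 -0.20; camera adjusted p = 0.102 with Benjamini-Hochberg). In the TCA cycle list, 6 of 20 genes were higher and 6 lower, with the succinyltransferase gene Dlst at log2 0.23. Fatty acid oxidation had 4 of 17 higher and 4 lower, with the carnitine transferase gene Cpt2 at -0.51 and the electron carrier gene Etfb at 0.42. Nucleotide synthesis and salvage had 4 of 21 higher and 1 lower (2 and 0 adjusted over the list alone), with the salvage genes Aprt at 0.52 and Hprt at 0.29. Cholesterol biosynthesis had 1 of 22 higher and 4 lower, with the reductase gene Dhcr7 at -0.59. LXR targets and lipid handling had 0 of 14 higher and 4 lower, with the acyltransferase gene Lpcat3 at -0.60. In the NRF2 and pentose phosphate list 8 of 17 were higher and 2 lower (9 and 2 adjusted over the list alone), with glutathione reductase Gsr at 0.91 (0.65 in E1 and 1.04 in E2), thioredoxin Txn1 at 0.48 and the pentose phosphate entry enzyme G6pdx at -0.58. Gsr was also higher in MIT within isotype (log2 1.87, edgeR adjusted p = 0.0182 with Benjamini-Hochberg). It was not enriched over isotype in MIT (log2 -0.15). For the other genes of this paragraph, levels against the controls are not given here. Iron and haem handling had 3 of 12 higher and 4 lower, with the ferritin gene Ftl1 at 0.43 and the ferritin receptor gene Ncoa4 at -0.56. Counts adjusted over the list alone equalled the others where none are given.

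Signalling and stress lists had members on both sides. So did all 14173 genes tested, of which 42.1% were called, 50% of these higher, so such counts alone say little about a list. Autophagy had 4 of 22 genes higher and 6 lower, with Gabarap, which coats autophagosomes, at log2 0.29 and the regulator Flcn at -0.54. Phagocytosis and efferocytosis had 1 of 13 higher and 4 lower. In this list, the engulfment gene Elmo1 was at 96.1 ± 25.5 CPM in MIT and 198 ± 15.9 in PMC (n = 5 each, log2 -1.08 ± 0.174, edgeR adjusted p = 0.00147 with Benjamini-Hochberg). The apoptotic cell binder Mfge8 was at 585 ± 31.7 against 828 ± 55.9 (log2 -0.54). Mfge8 was enriched over isotype in MIT (log2 1.41), and differed by log2 -0.59 within isotype and -0.94 within no-tag, neither past the threshold. For the other genes of this paragraph, levels against the controls are not given here. Mast cell cytokines and mediators had 5 of 20 higher and 2 lower, with the chemokine gene Ccl7 at 1362 ± 463 against 968 ± 336 CPM (log2 0.45) and the growth factor gene Csf1 at 62.3 ± 19.8 against 107 ± 44.1 (log2 -0.81). IgE receptor signalling had 3 of 17 higher and 9 lower, with the lipid phosphatase gene Inpp5d at -0.50. Interferon response had 8 of 16 higher and 1 lower (median log2 0.31), with the tetherin gene Bst2 at 238 ± 16.7 against 164 ± 14.9 CPM (log2 0.51). NF-kB targets had 1 of 14 higher and 6 lower, with the adhesion gene Icam1 at -0.43. Immediate early genes had 1 of 16 higher and 5 lower, with the phosphatase gene Dusp1 at -0.51. Unfolded protein response had 3 of 15 higher and 2 lower, with the degradation adaptor Sel1l at -0.61 and the chaperone Creld2 at 0.49. Heat shock had 2 of 8 higher and 2 lower, with the cytosolic chaperones Hsp90aa1 at 0.54 and Hspa8 at -0.44. Hypoxia had 1 of 13 higher and 4 lower, with the oxygen sensor Egln1 at 0.72 and the demethylase Kdm3a at -0.72. Apoptosis regulators had 4 of 15 higher and 2 lower, with the survival gene Mcl1 at 0.77 and the killer gene Bax at 0.49.

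Cell cycle genes had 0 of 29 higher and 0 lower by edgeR with Benjamini-Hochberg (median log2 -0.00). The cyclin gene Ccnd1 was at 1817 ± 124 CPM in MIT and 1801 ± 95.8 in PMC and Ccnd2 at 1562 ± 197 against 1403 ± 176 (n = 5 each). Of other cell types, basophil and eosinophil markers had 0 of 5 higher and 1 lower (Cd200r3, log2 -0.39), and lymphocyte markers 0 of 2 higher and 1 lower (Ighm, -0.87). Monocyte and macrophage markers had 1 of 6 higher and 2 lower (2 and 2 adjusted over the list alone). Nuclear noncoding RNAs had 0 of 3 higher and 1 lower (Kcnq1ot1, -0.74). Malat1 was at 291 ± 162 against 243 ± 146 CPM (log2 0.36 ± 0.555, edgeR adjusted p = 0.628 with Benjamini-Hochberg). No erythroid or fibroblast and mesothelial marker passed the expression filter. None of the lists from glycolysis to nuclear noncoding RNAs passed camera with Benjamini-Hochberg, the smallest adjusted p being 0.102. With the E code as an additive term, glycolysis, cholesterol biosynthesis and NRF2 targets passed it, though not with an estimated correlation.

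The larger single differences given next are of genes that averaged at least 10 CPM in the higher group. Among falls, the Mediator gene Med12 was 2.92-fold lower in MIT (6.93 ± 2.86 against 20.01 ± 2.51 CPM, n = 5 each, log2 -1.55 ± 0.244, -1.08 in E1 and -2.06 in E2, edgeR adjusted p = 0.00136 with Benjamini-Hochberg, chromosome X, 101274030 to 101297465). Il12rb2, a cytokine receptor chain, was 2.80-fold lower (29.6 ± 10.9 against 81.4 ± 10.1 CPM, log2 -1.49 ± 0.242, -1.13 in E1 and -1.88 in E2, edgeR adjusted p = 0.00152 with Benjamini-Hochberg, chromosome 6, 67291318 to 67376188). Polr2a, a subunit of RNA polymerase II, was 2.52-fold lower (28.2 ± 5.89 against 71.2 ± 12.6, log2 -1.33 ± 0.123, edgeR adjusted p = 0.000349 with Benjamini-Hochberg). Polr2a was depleted against isotype in MIT (log2 -0.89) and was also lower in MIT within the isotype pulldowns (log2 -1.42, edgeR adjusted p = 0.0412 with Benjamini-Hochberg). Others among the 8 largest falls were Sp2 (log2 -1.38), L1cam (-1.37), Exoc6b (-1.26), Gcnt2 (-1.24) and Nup188 (-1.23). Among rises, the membrane protein gene Tmem158 was 2.52-fold higher (45.5 ± 13.5 against 17.5 ± 1.96 CPM, log2 1.33 ± 0.192, 0.84 in E1 and 1.58 in E2, edgeR adjusted p = 0.000966 with Benjamini-Hochberg, chromosome 9, 123259053 to 123260764). The RNA-binding protein genes Sfpq and Ybx1 were 2.34-fold (59.3 ± 14.6 against 24.7 ± 2.55, log2 1.23 ± 0.127) and 2.27-fold higher (57.0 ± 17.2 against 24.6 ± 2.89, log2 1.18 ± 0.129). The chromatin remodeller gene Smarcd2 was 2.27-fold higher (40.3 ± 8.01 against 17.2 ± 2.67, log2 1.18 ± 0.156). The remaining rises were Samd11 (1.17), Tmem189 (1.16), Samd1 (1.15) and Jund (1.12). Of these 16 genes, only Tmem158 (log2 2.69) and Smarcd2 (1.73) were enriched over isotype in MIT. None was enriched over no-tag in MIT.

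Across all 14173 genes tested, 2978 were higher and 2983 lower in MIT, of which 147 and 165 differed by more than 2-fold, with a median size of log2 0.43 among the calls. With all 28 libraries in the fit, 10 were higher and 1 lower. Over all genes tested, the differences within E1 and within E2 libraries had r = 0.729 (Spearman 0.770; genes are not independent replicates). Among 388 genes enriched over both controls, 188 were higher and 57 lower in MIT, and among 2309 enriched over isotype 778 and 512. Fitted alone, with scaling and dispersion from these genes only, the sets gave 121 higher and 114 lower, and 685 and 717, so the lean to higher depended on the scaling and fit. Both sets were also picked with the same anti-HA libraries. More genes came in through MIT (1798 against 1432 in PMC over isotype, 456 against 352 over no-tag), so the picking itself favours a lean to higher.

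At 12 h, Kit was at 3593 ± 322 CPM in MIT and 6337 ± 280 in PMC (n = 2 each, log2 -0.87 ± 0.0932, edgeR adjusted p = 0.00639 with Benjamini-Hochberg). The RNA-binding protein gene Ybx1 was at 71.0 ± 19.7 against 27.2 ± 2.20 (log2 1.33 ± 0.201). At 24 h, the nerve growth factor receptor gene Ngfr was at 23.8 ± 2.77 against 56.7 ± 6.08 CPM (n = 3 each, log2 -1.28 ± 0.139, edgeR adjusted p = 0.00284 with Benjamini-Hochberg). Tmem158 was then at 43.1 ± 13.3 against 16.3 ± 0.405 (log2 1.38 ± 0.243). Ribosomal protein genes were higher by a median log2 of 0.56 at 12 h (50 of 54 called, 51 adjusted over the list alone; camera adjusted p = 2.08e-25 with Benjamini-Hochberg; adjusted p = 0.495 with an estimated correlation). At 24 h the median was 0.29 (35 called, 44 adjusted over the list alone; camera adjusted p = 2.25e-10; adjusted p = 0.603 with an estimated correlation). Mast cell genes had a median of -0.34 at 12 h (0 higher, 9 lower; 0 and 12 adjusted over the list alone) and -0.17 at 24 h (3 and 8; 4 and 12 adjusted over the list alone). In all, 1133 genes were higher and 1280 lower at 12 h, and 1979 and 1917 at 24 h. Leaving out 1 library moved these counts. At 12 h they became 177 and 205 without PMC replicate 1, 134 and 116 without MIT replicate 2, 0 and 1 without PMC replicate 2, and 1675 and 2295 without MIT replicate 1. At 24 h they became 965 and 999 without PMC replicate 1, 948 and 1172 without PMC replicate 2, 1223 and 1162 without PMC replicate 3, 498 and 540 without MIT replicate 2, and 467 and 514 without MIT replicate 3.

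Calls at 12 h and 24 h overlapped. Of the genes called higher in MIT at 12 h, 918 were also called at 24 h (158 expected if independent), and 1077 of those called lower (173 expected), with 0 in opposite directions. Across genes, which are not independent replicates, r was 0.762 and Spearman 0.787. For the difference between the 24 h and 12 h effects, edgeR with Benjamini-Hochberg called 0 genes (278 at an unadjusted p under 0.05; DESeq2 called 0, and edgeR without a filter on low counts 1).

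From 12 to 24 h, transcripts of an enzyme of peptide ends and of a tryptase fell in both cell groups. Qpct, glutaminyl cyclase, fell by 1.79 on the log2 scale in PMC (8.76 ± 1.06 at 24 h, n = 3, against 29.6 ± 4.44 CPM at 12 h, n = 2, SE 0.133, edgeR adjusted p = 0.000752 with Benjamini-Hochberg). In MIT it fell by 1.57 (7.76 ± 0.636 against 22.9 ± 2.69). Tpsab1, a granule tryptase, fell by 0.92 in PMC (1091 ± 61.6 against 2011 ± 35.0 CPM) and by 0.94 in MIT (1049 ± 99.2 against 1992 ± 10.2). Ccl7 fell by 0.92 in PMC and fell by 0.86 in MIT. Lst1, a leukocyte adaptor, rose by 1.22 in PMC (66.3 ± 0.682 against 27.8 ± 2.96 CPM, SE 0.113, edgeR adjusted p = 0.00225 with Benjamini-Hochberg). In MIT it rose by 1.35 (92.6 ± 6.79 against 36.0 ± 4.08). The actin crosslinker gene Flna rose by 1.2 in PMC (127 ± 5.27 against 53.9 ± 6.06 CPM, edgeR adjusted p = 0.000413 with Benjamini-Hochberg). The adaptor gene Lat fell by 0.81 there, and in MIT Flna rose by 0.87 and Lat fell by 0.70. Fcer1a rose by 0.75 in MIT (5322 ± 310 against 3137 ± 289 CPM, SE 0.106) and by 0.52 in PMC, and the histamine-forming enzyme gene Hdc fell by 0.70 in MIT and fell by 0.80 in PMC. In PMC, the Fcer1a call was lost without 12 h replicate 2 (log2 0.39) or 24 h replicate 1 (0.53), 2 (0.52) or 3 (0.52), and that of Hdc without 12 h replicate 1 (-0.79) or 2 (-0.78) or 24 h replicate 2 (-0.75). In MIT, the ribosomal protein genes Rps15a fell by 0.82 (60.0 ± 3.50 against 105 ± 11.1) and Rps6 fell by 0.71, while their log2 differences of -0.41 and -0.35 in PMC did not pass. Kit was at log2 -0.09 in PMC and -0.07 in MIT, Cpa3 at 0.26 and 0.42, and Mcpt4 at -0.14 and -0.11, none past the threshold. Tpsab1 and the other tryptase gene Tpsb2 may share some reads. How many was not tested, so the level of either is uncertain. Among the genes above, Fcer1a, Cpa3 and Mcpt4 were enriched over isotype in both cell groups and Ccl7 in MIT, and Tpsab1 was depleted in both.

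In PMC, 94 genes were higher and 140 lower at 24 h, 234 in all. With the E code as an additive term these were 764 and 787, and with all 28 libraries in the fit 0 and 0. Without 1 library the total was 73 (12 h replicate 1), 10 (12 h replicate 2), 44 (24 h replicate 1), 22 (24 h replicate 2) or 48 (24 h replicate 3). In MIT, the E code term gave 1147 higher and 1143 lower, and all 28 libraries in the fit 0 and 0. The main fit there called 383 higher and 482 lower, 865 in all. This became 414 without 12 h replicate 2, 504 without 24 h replicate 1, 281 without 24 h replicate 2 and 278 without 24 h replicate 3. Called in both cell groups were 81 rises (2.54 expected if independent) and 120 falls (4.76 expected). The opioid peptide precursor gene Penk, at 21.6 ± 11.6 against 192 ± 176 CPM in MIT (log2 -3.15 ± 0.668), lost its call without MIT 12 h replicate 2 (log2 -1.68), or 24 h replicate 1 (-2.77), 2 (-3.37) or 3 (-3.42). Targets of amino acid stress and ATF4 had 0 of 24 higher and 6 lower in PMC (0 and 18 adjusted over the list alone, median log2 -0.43; camera adjusted p = 2.73e-11 with Benjamini-Hochberg; adjusted p = 0.535 with an estimated correlation). In MIT they had 0 and 6 (0 and 11 adjusted over the list alone, median log2 -0.35; camera adjusted p = 5.2e-08; adjusted p = 0.506 with an estimated correlation). Ribosomal protein genes had 0 of 54 higher and 0 lower in PMC by edgeR with Benjamini-Hochberg (0 and 2 adjusted over the list alone, median log2 -0.18; camera adjusted p = 2.02e-08; adjusted p = 0.758 with an estimated correlation). In MIT they had 0 higher and 41 lower (0 and 50 adjusted over the list alone, median log2 -0.42; camera adjusted p = 8.46e-31; adjusted p = 0.37 with an estimated correlation). Cytokines and mediators had 0 of 20 higher and 2 lower in PMC (1 and 8 adjusted over the list alone, median log2 -0.40; camera adjusted p = 0.00312; adjusted p = 0.496 with an estimated correlation). In MIT they had 1 and 5 (1 and 7 adjusted over the list alone, median log2 -0.22; camera adjusted p = 0.0208; adjusted p = 0.37 with an estimated correlation). Heat shock genes had 0 of 8 higher and 3 lower in MIT (0 and 4 adjusted over the list alone; camera adjusted p = 0.000702; adjusted p = 0.37 with an estimated correlation), with the mitochondrial chaperone gene Hspd1 falling at log2 -0.46. NRF2 targets and pentose phosphate had 0 of 17 higher and 0 lower in MIT by edgeR with Benjamini-Hochberg (0 and 0 adjusted over the list alone, median log2 -0.33; camera adjusted p = 0.00667; adjusted p = 0.783 with an estimated correlation).

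Against the isotype antibody, the anti-HA pulldown held more of several granule transcripts and less of mitochondrial and nuclear RNA. In MIT, Tpsb2, a tryptase gene, was at 65380 ± 9080 CPM in anti-HA and 29030 ± 7050 in isotype (n = 5 each, log2 1.36 ± 0.193, edgeR adjusted p = 4.73e-07 with Benjamini-Hochberg). The chymase gene Cma1 was at 34050 ± 1510 against 15690 ± 5600 (log2 1.30 ± 0.210), and the granule membrane gene Cd63 at 7418 ± 989 against 3052 ± 996 (log2 1.48 ± 0.199). Tpsab1, the tryptase gene that may share reads with Tpsb2, was instead depleted (log2 -0.78 in MIT and -1.40 in PMC). mt-Co1, made and translated within mitochondria, was at 10.7 ± 2.44 against 825 ± 222 CPM (log2 -6.12 ± 0.310, edgeR adjusted p = 1.69e-17 with Benjamini-Hochberg). Malat1, a nuclear RNA, was at 291 ± 162 against 37460 ± 21900 (log2 -6.75 ± 1.10). In PMC, Tpsb2 was at 59110 ± 6000 against 31480 ± 11600 CPM (log2 1.09 ± 0.191). There mt-Co1 was at 12.8 ± 2.65 against 940 ± 555 (log2 -5.96 ± 0.307) and Malat1 at 243 ± 146 against 20470 ± 12700 (log2 -6.11 ± 1.06). Rpl22 was enriched in MIT (log2 1.76 ± 0.467, edgeR adjusted p = 0.00275 with Benjamini-Hochberg), a call lost without MIT isotype 12 h replicate 2 (log2 1.42). In PMC it was at log2 0.02 (edgeR adjusted p = 0.986 with Benjamini-Hochberg). Mitochondrially encoded mRNAs had 0 of 7 higher and 7 lower in both cell groups (camera adjusted p = 3.16e-18 in MIT and 2.9e-22 in PMC; adjusted p = 0.00777 and 0.00284 with an estimated correlation). Mast cell genes had 11 of 22 higher and 1 lower in MIT and 10 and 1 in PMC (camera adjusted p = 0.0012 and 0.0119; adjusted p = 0.369 and 0.466 with an estimated correlation). Nuclear OXPHOS genes had 33 of 38 higher in MIT and 31 in PMC, and lysosome genes 20 and 22 of 34.

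In MIT, 1798 genes were higher in anti-HA than in isotype and 2823 lower, and in PMC 1432 and 2387. Of the MIT calls 38.9% were higher, against 18.8% with RLE factors (815 and 3518) and 8.75% with DESeq2 (1102 and 11488). The median of all genes tested was log2 -0.07, against -0.46 with RLE factors. With DESeq2 it was -5.04, but over more genes, since low counts were not filtered there. In PMC the share was 37.5%, against 17.1% with RLE factors (606 and 2945, median -0.35) and 8.89% with DESeq2 (1045 and 10711, median -5.34, again over more genes). With the anti-HA libraries thinned to the median control total, 918 were higher and 1539 lower in MIT, and 532 and 1104 in PMC. The number enriched in MIT became 3518 without isotype 12 h replicate 1, 2933 without isotype 24 h replicate 1 and 949 without isotype 12 h replicate 2. In PMC it became 881 without anti-HA 12 h replicate 1, 916 without anti-HA 12 h replicate 2, 2823 without isotype 12 h replicate 1 and 2181 without isotype 12 h replicate 2. The largest fitted rises rested on few control counts, such as Msl3 in MIT with 6409 counts in anti-HA and 16 in isotype.

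Against anti-HA from cells without the tag, Mcpt4 was enriched in both cell groups (log2 1.07 ± 0.246 in MIT and 1.02 in PMC, n = 5 against 4, edgeR adjusted p = 0.00174 in MIT with Benjamini-Hochberg). Kit (log2 0.06, edgeR adjusted p = 0.914 with Benjamini-Hochberg) and Cpa3 (0.11; 0.849) were not in MIT. Mast cell genes had 3 of 22 higher and 0 lower in each cell group, and mitochondrially encoded mRNAs 0 of 7 higher and 7 lower (camera adjusted p = 4.9e-37 in MIT and 1.85e-31 in PMC; adjusted p = 0.000159 and 0.00042 with an estimated correlation). In MIT 456 genes were higher in anti-HA from RiboTag cells and 1530 lower, and in PMC 352 and 1415. Of these calls 23.0% and 19.9% were higher. With the anti-HA libraries thinned to the median control total, 70 were higher and 342 lower in MIT, and 40 and 330 in PMC. With RLE factors the share was 12.4% in MIT (243 and 1719, median of all genes -0.18) and 8.44% in PMC (152 and 1648, -0.19). With DESeq2, again over more genes without a filter on low counts, it was 8.96% (653 and 6631, -1.09) and 6.07% (494 and 7640, -2.61). The number enriched in MIT became 1419 without no-tag 12 h replicate 1, 1395 without no-tag 12 h replicate 2, 1626 without no-tag 24 h replicate 1, 702 without no-tag 24 h replicate 2, 246 without anti-HA 12 h replicate 1 and 218 without anti-HA 12 h replicate 2. In PMC it became 1003 without no-tag 12 h replicate 1, 785 without no-tag 24 h replicate 1, 192 without no-tag 24 h replicate 2, 221 without anti-HA 12 h replicate 1 or 24 h replicate 1, 213 without anti-HA 12 h replicate 2, 211 without 24 h replicate 2 and 206 without 24 h replicate 3.

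Neutrophil transcripts were present in the MIT anti-HA libraries at low levels, and far above PMC. S100a8, a calprotectin gene, had 530 pooled counts in MIT anti-HA and 7 in PMC anti-HA (3.32 against 0.0361 CPM, ratio 92.1, 95% counting interval 44.4 to 230, n = 5 libraries each). S100a9, its partner, had 393 and 1 (ratio 478, interval 85.3 to 18900). The granule protein genes had 596 and 2 (Ngp, ratio 362, interval 99.9 to 3000), 217 and 8 (Ltf, ratio 33.0, interval 16.4 to 77.4) and 47 and 1 (Lcn2, ratio 57.2, interval 9.77 to 2300). Retnlg, a resistin-like gene of neutrophils, had 140 and 0. The 95% counting interval of its ratio began at 45.5, and against 3 counts it was 56.7-fold higher. Of 15 neutrophil markers tested, 11 were higher and 0 lower in MIT (11 and 0 adjusted over the list alone; camera adjusted p = 0.000213 with Benjamini-Hochberg on edgeR's log2 CPM; adjusted p = 0.603 with an estimated correlation). Over all 26 neutrophil genes the pooled level was 21.8 CPM in MIT anti-HA and 6.91 in PMC anti-HA, and Mmp9 (220 and 233 counts), Mmp25 (121 and 232) and Ctsg (487 and 660) were not higher in MIT. Summed over the 11 genes called higher, the level was 16.1 ± 15.5 CPM in MIT anti-HA and 0.720 ± 0.456 in PMC anti-HA (n = 5 each). It was 2804 ± 1770 in MIT isotype, 69.6 ± 43.9 in PMC isotype, 1351 ± 1360 in MIT no-tag and 363 ± 692 in PMC no-tag (n = 4 for no-tag). Without 12 h replicate 2 of the group, the mean was 17.1 in PMC no-tag, 681 in MIT no-tag and 9.38 in MIT anti-HA. S100a8 itself was at 3.54 ± 3.40 CPM in MIT anti-HA and 842 ± 381 in MIT isotype (log2 -7.73 ± 0.902, edgeR adjusted p = 1.46e-06 with Benjamini-Hochberg). In MIT, 17 of 18 neutrophil markers were depleted in anti-HA against isotype.

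**Figure D4:**
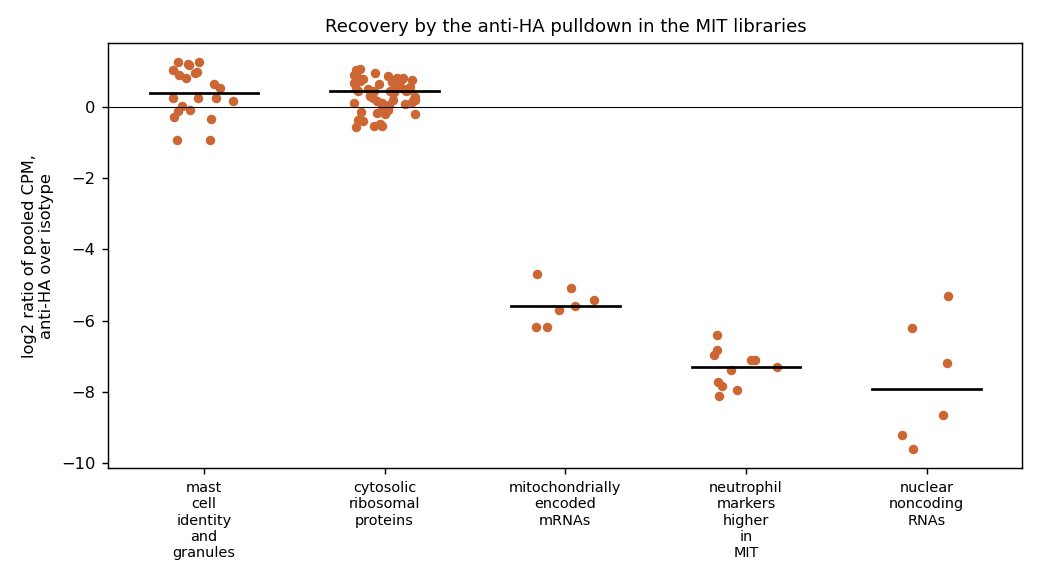
Log2 ratio of pooled CPM in MIT anti-HA over MIT isotype libraries for single genes of 5 groups, with the group median as a bar. Medians are 0.40 for mast cell genes, 0.44 for ribosomal protein genes, -5.60 for mitochondrially encoded mRNAs, -7.31 for neutrophil genes and -7.91 for nuclear noncoding RNAs.

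Within the isotype pulldowns, S100a8 differed between the cell groups, at 842 ± 381 CPM in MIT and 9.18 ± 11.1 in PMC (n = 5 each, log2 7.01 ± 1.01, edgeR adjusted p = 0.00213 with Benjamini-Hochberg). Xpot, a tRNA exporter gene, was at 54.7 ± 26.8 against 169 ± 35.2 CPM (log2 -1.76 ± 0.338, edgeR adjusted p = 0.00536 with Benjamini-Hochberg), a call lost without MIT 12 h replicate 2 (log2 -1.39). Kit was at log2 -1.03 (edgeR adjusted p = 0.00945 with Benjamini-Hochberg), a call lost without PMC 12 h replicate 1 (log2 -1.01) or MIT 12 h replicate 2 (-0.86). In all, 60 genes were higher and 56 lower in MIT (51.7% higher). The share was 57.9% with RLE factors and 58.2% with DESeq2, where the median of all genes was log2 0.15 and 0.24. Voom with sample quality weights called 6 higher and 0 lower, the E code as an additive term 96 and 96, and DESeq2 283 and 203. Of 18 neutrophil markers, 11 were higher (17 adjusted over the list alone; camera adjusted p = 2.67e-21; adjusted p = 0.00837 with an estimated correlation). The total of 116 became 178 without MIT 24 h replicate 1, 46 without PMC 12 h replicate 1, 63 without MIT 12 h replicate 2, 190 without PMC 12 h replicate 2 and 75 without PMC 24 h replicate 3. Within the no-tag pulldowns, Polr2a was at 30.0 ± 15.4 CPM in MIT and 153 ± 40.3 in PMC (n = 4 each, log2 -2.49 ± 0.403, edgeR adjusted p = 0.00066 with Benjamini-Hochberg). There 16 genes were higher and 20 lower, against 3 and 0 by voom with sample quality weights. Of 18 neutrophil markers, 4 were higher (14 adjusted over the list alone; camera adjusted p = 1.86e-13; adjusted p = 0.0621 with an estimated correlation). With DESeq2 34.6% of the no-tag calls were higher, against 44.4%. The total of 36 became 350 without PMC 12 h replicate 1, 93 without MIT 12 h replicate 2 and 13 without PMC 24 h replicate 2.

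Whether the difference between MIT and PMC was larger in anti-HA than in the controls was tested directly. Kit differed by log2 -0.86 in anti-HA and -1.03 in isotype. For the difference between the effect in anti-HA and in isotype, edgeR with Benjamini-Hochberg called 0 genes (904 at an unadjusted p under 0.05; 48 by DESeq2), and 3 without MIT isotype 12 h replicate 2. For anti-HA against no-tag it called 0 (679 at an unadjusted p under 0.05; 0 by DESeq2; 4 without a filter on low counts), and 40 without PMC no-tag 12 h replicate 1. Of simulated 2-fold differences, 3.45% were found in the comparison with isotype, so most of that size would be missed.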

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

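Chosen only after the result was seen were the tests of neutrophil RNA and those of unspecific RNA for ribosomal protein genes. The tests of transcript length were added after the data were seen, but before their own outcome.

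A difference between the effects in separate groups, by camera on the interaction term with Benjamini-Hochberg on edgeR's log2 CPM, drew attention to 12 list medians. None of the 12 passed with an estimated correlation, where the smallest camera adjusted p was 0.0623. No group had 4 to 10 libraries, as the largest had 3, so single libraries were not tested as outliers. All data were part of a comparison.

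For the MIT against PMC effect at 24 h minus that at 12 h, mast cell identity and granules had a median log2 of 0.105 (camera adjusted p = 0.00665, adjusted p = 0.74 with an estimated correlation). Fatty acid oxidation had 0.0943 (camera adjusted p = 0.0361, adjusted p = 0.642 with an estimated correlation) and autophagy 0.116 (camera adjusted p = 0.0497, adjusted p = 0.74 with an estimated correlation). Nucleotide synthesis and salvage had -0.163 (camera adjusted p = 0.00112, adjusted p = 0.74 with an estimated correlation), interferon response -0.149 (camera adjusted p = 0.00665, adjusted p = 0.74 with an estimated correlation) and heat shock -0.231 (camera adjusted p = 6.08e-05, adjusted p = 0.385 with an estimated correlation). For these 6 lists no explanation was tested. Cytosolic ribosomal proteins had -0.262 (camera adjusted p = 3e-33, adjusted p = 0.394 with an estimated correlation), and neutrophil markers had a fitted median of -0.693 (camera adjusted p = 0.00463, adjusted p = 0.74 with an estimated correlation), which rests on few PMC counts and is no bound.

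For the effect in anti-HA minus that in isotype, neutrophil markers had a fitted median of -0.721 (camera adjusted p = 1.9e-13, adjusted p = 0.0623 with an estimated correlation) and cytosolic ribosomal proteins 0.39 (camera adjusted p = 8.26e-05, adjusted p = 0.96 with an estimated correlation). For anti-HA minus no-tag, the neutrophil markers had -0.148 (camera adjusted p = 3.1e-06, adjusted p = 0.714 with an estimated correlation) and the ribosomal proteins 0.234 (camera adjusted p = 0.000206, adjusted p = 0.928 with an estimated correlation).

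Neutrophil transcripts in the MIT anti-HA libraries may be unspecific RNA carried through the pulldown. Their median log2 ratio of anti-HA over isotype was -7.31 over 11 genes (range -8.13 to -6.41, or 0.629% at the median), under the highest ratio of mitochondrially encoded mRNAs, -4.69, which cytosolic ribosomes do not bind. The 5th percentile of the mast cell genes' ratios was -0.905, so most of the neutrophil RNA was not pulled down as mast cell transcripts were. Translation of a small part on tagged mast cell ribosomes cannot be told from this ratio, because neutrophil RNA in the isotype pulldowns lowers it in any case. For the 11 neutrophil genes higher in MIT in the isotype pulldowns, PMC anti-HA held 11.9% of the MIT anti-HA level. This argues against wrongly assigned reads spread evenly over the libraries, but would miss reads passed among MIT libraries only. The labels name a sort of the mast cells from the co-cultures, which would remove free neutrophils. Whether the RNA came from neutrophils bound to or taken up by mast cells, which the co-culture design names, stays open and was not tested.

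Ribosomal protein transcripts were higher in MIT by a median log2 of 0.40, and transcript length could have contributed, because the log2 difference fell with length (Spearman -0.227 across 14121 genes, which are not independent replicates). With the length trend removed per library the ribosomal list kept a median of 0.285 (camera adjusted p = 1.48e-13, adjusted p = 0.6 with an estimated correlation). Nuclear OXPHOS kept 0.181 of 0.33 (camera adjusted p = 7.37e-05, adjusted p = 0.6 with an estimated correlation). The bin of shortest genes (median 545 bases) itself had a median log2 difference of 0.29. The removal used annotated lengths, which may differ from those of the transcripts present and so leave part of a length effect. It therefore cannot tell whether length was the whole cause of either. More unspecific RNA in MIT anti-HA is argued against, since at 3.88%, the highest share that the mitochondrial mRNAs allow, RNA of any MIT control library would raise the list by a median log2 of at most 0.0304. The same difference in unspecifically bound RNA is argued against by this bound and by the isotype pulldowns, with a median of -0.00459 (-0.322 to 0.179 when 1 library was left out), though not by the no-tag pulldowns alone (0.141, -0.151 to 0.343). The median of all genes tested was log2 0.0174 (0.015 with RLE factors). Both scalings place this median near 0 by design, so it cannot tell whether the scaling shifted all genes. The difference in ribosome-bound RNA by co-culture, which the design names, stays open and is a hypothesis only. Transcript length, the scaling and the depth of the libraries stay open as well.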

How the results depend on the processing

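Genes enriched over isotype, MIT 24 h replicates 2 and 3 summed, thinned anti-HA libraries and the transcript length trend were chosen only after the data were seen. No named gene past the threshold reversed under any alternative run, which left out the separate 12 h and 24 h effects. In comparisons with or within the controls, only genes always named or with the largest changes were run. No list test reversed with the E code term, only enriched genes or the length trend removed. Under fry and the estimated correlation, the direction of the lists was not compared. Which direction held more calls did change, as for time in PMC, with 94 higher and 140 lower, but 34 and 20 with only genes enriched over both controls.

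With all 28 libraries in the fit, the count of MIT against PMC was 10 higher and 1 lower over both times, 3 and 0 at 12 h, and 3 and 0 at 24 h, and 24 h against 12 h gave 0 in PMC and 0 in MIT; the controls' larger spread then enters the shared dispersion. With only genes enriched over both controls, where scaling and dispersion changed along with the genes tested, the counts were 121 and 114, 86 and 85, 82 and 81, then 54 and 75. With only genes enriched over isotype they were 685 and 717, 430 and 403, 477 and 552, then 132 and 398.

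The E code as an additive term gave 2219 higher and 2542 lower at 12 h, 2961 lower at 24 h, 1551 and 2290 for time in PMC and MIT, and 192 and 60 for MIT against PMC in isotype and no-tag. In PMC and MIT residuals, 8 of 10 libraries correlated best with their own replicate number and 10 of 10 with their own E code, so the numbers alone did not pair the libraries. Nor did the E code for every pair, as r ran from -0.0377 to 0.441 in the 19 pairs that share it. Still, 15 of these had r over 0.1, against 0 of the 18 pairs with different codes (-0.441 to -0.00437). The 2 residuals of a 12 h group mirror each other, so the pairs are not independent. With this term camera with Benjamini-Hochberg gained glycolysis (adjusted p = 0.0428), cholesterol biosynthesis (0.0299) and NRF2 targets (0.0322) for MIT against PMC over both times, with adjusted p = 0.613, 0.613 and 0.609 with an estimated correlation. For time it gained cholesterol biosynthesis (0.00116), NRF2 targets (0.00419) and unfolded protein response (0.00173) in PMC by camera, with adjusted p = 0.76, 0.727 and 0.76 with an estimated correlation. In MIT camera gained unfolded protein response (0.012) and cell cycle (0.0438), with adjusted p = 0.819 and 0.839 with an estimated correlation. For the difference between the times' effects, camera gained mitochondrially encoded mRNAs (0.0239) and NRF2 targets (0.00335), with adjusted p = 0.59 and 0.386 with an estimated correlation. With the length trend removed, camera gave glycolysis 0.0822, cholesterol biosynthesis 0.433 and NRF2 targets 0.135 over both times. Voom with sample quality weights gave 481 and 571 at 12 h, 3712 and 3582 at 24 h, 469 and 360 for time, and 6 and 3 within the controls. Summing MIT 24 h replicates 2 and 3 gave 542 and 603 at 24 h, and 116 and 277 for time. DESeq2 gave 682 and 1331 for time, 1102 for anti-HA over isotype in MIT, 48 for the effect in anti-HA minus isotype, and 486 and 283 within isotype and no-tag. The cause was not tested for these.

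Without a filter on low counts, 1 gene differed between the effects at 24 h and 12 h, 957 and 1389 with time in PMC and MIT, 6312 and 3886 were enriched over isotype and no-tag in MIT and 5761 and 3130 in PMC, 4 differed between anti-HA and no-tag effects, and 89 within no-tag. A filter of 5 CPM, which tests fewer genes, gave 3117, 1276, 2184 and 764 for the same 4 enrichments and 77 within no-tag. RLE factors gave 815, 243, 606 and 152, and thinned anti-HA libraries, which carry fewer counts, 918, 70, 532 and 40.

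Leaving out 1 library gave 2131 to 3068 higher and 2213 to 3568 lower over both times, 0 to 1675 and 1 to 2295 at 12 h, and 467 to 2238 and 514 to 2527 at 24 h. It gave 0 to 0 for the difference between these times' effects, 10 to 73 for time in PMC and 278 to 875 in MIT. Enrichment was 949 to 3518 over isotype and 218 to 1626 over no-tag in MIT, and 881 to 2823 and 192 to 1003 in PMC. Effects in anti-HA minus isotype gave 0 to 3, anti-HA minus no-tag 0 to 40, and MIT against PMC 46 to 190 within isotype and 13 to 350 within no-tag. Where this left a group with 1 library, that library was assumed to vary like the others.

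For the genes named by rule, each under each alternative, 2366 values for MIT against PMC over both times kept direction and side of the threshold, 201 lost the threshold and 4 gained it. For time these were 1079, 155 and 29 in PMC and 1045, 254 and 27 in MIT. For the controls, only genes always named or with the largest changes were run. Over isotype the values were 448, 3 and 6 in MIT and 431, 12 and 4 in PMC. Over no-tag they were 421, 4 and 1 in MIT, and 398, 15 and 3 in PMC. Within isotype they were 349, 54 and 5, and within no-tag 302, 61 and 12. Of the list tests, 474 kept it, 43 lost it, including every list called for MIT against PMC over both times with an estimated correlation, and 23 gained it.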

Other observations

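The tests of Xist and Y-linked transcripts, the bins by transcript length and the 16 gene families were chosen only after the results were seen, and the splits of the libraries before.

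Xist, the RNA that coats the inactive X chromosome, was at 66.1 CPM or more in all 8 no-tag libraries (up to 1040), and at 28.9 CPM or less in the 20 RiboTag libraries. Ddx3y, on the Y chromosome, was at 0 to 22 CPM in the no-tag and 57.7 to 154 in the RiboTag libraries. These levels fit cells of mice of the other sex in the no-tag pulldowns, with a lowest Xist level of 66.1, and single libraries with swapped labels are argued against because 0 libraries lay on the other side for Xist or Ddx3y. Any transcript that differs between the sexes may thus pass as enriched or depleted over no-tag, as 4 of 5 Y-linked genes did over no-tag and 0 of 5 over isotype. Differences of the no-tag libraries were not limited to the sex chromosomes. Herpud1, on chromosome 8, was depleted in anti-HA over no-tag (log2 -2.10 in MIT and -1.81 in PMC). Over isotype it was at 0.49 and 0.37, neither past the threshold. Whether such differences follow sex or another trait of these cells was not tested. Ctsg, a serine protease gene, was at 123 ± 96.3 CPM in MIT no-tag and 112 ± 80.8 in PMC no-tag (n = 4 each), against 5.27 ± 7.75 and 6.62 ± 6.42 in isotype and 3.06 ± 1.34 and 3.56 ± 1.11 in anti-HA (n = 5 each).

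For MIT against PMC in anti-HA over both times, 1 of 60 splits of the libraries, the real one, called as many genes (5961, against 4 in the highest other). This argues against chance only if the libraries are separate samples, which the labels do not state. For 24 h alone the 10 splits are too few for a share under 0.05 (real count 4723, highest other 0). Under the same assumption, chance is argued against for anti-HA against isotype in MIT (7061 genes in the libraries compared, highest other 509) and in PMC (8061, highest other 0). So it is for anti-HA against no-tag in MIT (2584, highest other 0) and PMC (3796, highest other 422), each with 1 of 60 splits. Chance cannot be excluded for the number of genes called for MIT against PMC in isotype (18 genes, with 3 of 60 splits calling as many, highest other 23). That leaves aside how far single genes differed. In no-tag the 18 splits are too few (1 called as many; real count 3, highest other 2). For the effect in anti-HA minus isotype, 13 of 40 splits called as many as the real 2 genes, and for anti-HA minus no-tag 6 of 40 called as many as the real 10, so chance cannot be excluded for either. Their highest other counts, 78 and 95, point to a structure of the samples, whose source was not tested. The split with 95 parted E1 from E2 as far as any of the 40, the split with 78 did not, and with the E code as an additive term the fit of all 28 libraries called 0 and 0 genes by edgeR. Each of these counts comes from a fit of only the libraries it splits.

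Gene families chosen by symbol, some of which share members with the lists, leaned to higher or lower in MIT anti-HA over both times, with camera and Benjamini-Hochberg over 16 families on edgeR's log2 CPM. Mitochondrial ribosomal protein genes had 55 of 76 higher and 1 lower (median log2 0.28; camera adjusted p = 8.38e-11; adjusted p = 0.179 with an estimated correlation), and proteasome subunits 25 of 38 higher and 0 lower (median log2 0.19, camera adjusted p = 2.65e-05, adjusted p = 0.32 with an estimated correlation). Heterogeneous nuclear ribonucleoproteins had 15 of 20 higher and 0 lower (median log2 0.34, camera adjusted p = 3.04e-05, adjusted p = 0.147 with an estimated correlation), spliceosomal Sm and U snRNP proteins 11 of 13 and 0 (median log2 0.35, camera adjusted p = 0.000117, adjusted p = 0.237 with an estimated correlation), and SR splicing factors 5 of 10 and 0 (median log2 0.30, camera adjusted p = 0.00241, adjusted p = 0.147 with an estimated correlation). Zinc finger genes named Zfp had 17 of 308 higher and 118 lower (median log2 -0.28, camera adjusted p = 2.65e-07, adjusted p = 0.196 with an estimated correlation), solute carriers 20 and 77 of 179 (median log2 -0.26, camera adjusted p = 2.65e-05, adjusted p = 0.147 with an estimated correlation), aminoacyl tRNA synthetases 1 and 11 of 19 (median log2 -0.22, camera adjusted p = 0.00171, adjusted p = 0.502 with an estimated correlation), and nucleoporins 1 and 9 of 19 (median log2 -0.18, camera adjusted p = 0.00576, adjusted p = 0.53 with an estimated correlation). The other 7 families did not pass. In 10 bins of genes by transcript length, the shortest (median 545 bases) had a median log2 difference of 0.29, and bin 8 (median 4455 bases) -0.15.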
